A study of Homo sapiens with 18 samples.

How the data were processed

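Chromatin accessibility was measured by bulk ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in neurons made from the human embryonic stem cell line H1 (WA01). Glutamatergic neurons (Glu) were induced with Ngn2 and GABAergic neurons (GABA) with Ascl1 and Dlx2, per the labels' protocols. They were grown with mouse glia, silenced with tetrodotoxin and DL-AP5, and then depolarised with potassium chloride (KCl). The labels list 18 libraries, which fall into 6 groups of 3 by cell type and time after KCl. The middle time was 30 min in the time label, while the sample titles give 45 min for the same libraries. It is called 30 min here, after the time label, and the difference could not be settled from the files. Nothing in the labels says whether the 3 libraries of a group came from separate cultures.

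The files analysed were 1 peak list per group, so no value per library entered any comparison. The submitters' processing notes name cutadapt, Bowtie2 and MACS2, with no versions, and the builds hg38 and mm10, with no role given for either. How the libraries of a group were pooled for calling, how mouse reads were removed and whether insertion sites were shifted are not given in the sources used here. Each deposited list held regions kept by the authors at an irreproducible discovery rate (IDR) of 0.05. The deposited IDR score of a peak was a whole number from 540 up to a cap of 1000. The deposited fold enrichment is the ratio of the signal at the summit to the local background of the authors' peak caller. The deposited −log10 p at the summit is from the same caller, and its lowest value differed between the lists, from 14.0 in the Glu list at 0 min to 28.2 in the GABA list at 90 min. These scores are the authors' own values per peak and were used to describe peaks and to rank or filter them within a list. Scores from different lists set side by side describe those lists only. Read depth per library is not in the peak lists and is unknown here.

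A deposited list repeats a region once per summit, so entries that overlapped by at least 1 bp were merged, and each merged peak kept the fold and summit of its entry with the highest fold. A peak was called shared with another list when a merged peak there overlapped it by at least 1 bp (bedtools 2.31.1). Gained peaks were peaks of a later list with no overlapping peak at 0 min, and lost peaks were peaks at 0 min with no overlapping peak in the later list. Glu-only and GABA-only peaks had no overlapping peak in the other cell type's list of the same time. Peaks of 1 cell type "at all 3 times" were 0 min peaks found again at 30 and 90 min that overlapped no peak of the other cell type at any time. A percentage of peaks is given with its 95% Wilson interval, and the percentage near a gene list with its exact binomial interval. Both cover counting error over peaks only, not variation between cultures, and neighbouring peaks are not independent. With 1 list per group no replicate test could be made, and no p-value is given.

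Gene positions came from a RefSeq table of GRCh38.p14, which is the same build as hg38. A test of the build found a peak within 1 kb of an annotated end of 62.4% to 66.9% of 19974 protein-coding genes, and of 10.1% to 12.5% when the gene positions were shifted by 100 kb. The table has no strand. The distances planned from the transcript start were therefore measured from either annotated end of a gene, and a distal peak was one with its summit over 1 kb from every annotated gene end. A peak was counted as near a gene when its summit lay within 50 kb of either end. The motif analysis planned with 20 fixed consensus sequences needs the genome sequence and was not run.

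Before the data were examined, 19 gene lists were fixed: immediate-early and late-response genes, glutamatergic, GABAergic, pan-neuronal, sensory and monoaminergic or cholinergic markers, pluripotency, astrocyte, oligodendrocyte, microglia, fibroblast and progenitor markers, forebrain and mid-hindbrain patterning genes, glutamate receptors, GABA-A receptors, voltage-gated channels and housekeeping genes. Each of their 290 genes was found in the table, 1 of them under a newer symbol, and 6 genes are in more than 1 list. For each list and contrast, the peaks of both kinds within the windows were counted once each. The percentage of the first kind was set beside that over all protein-coding genes. The planned median over genes of log2((a + 1)/(b + 1)), where a and b are a gene's peaks of each kind, was 0 for most lists. The ratio of the counts summed over genes was therefore used as well, a choice made after seeing the data. In these sums a peak near more than 1 gene of a list counts once for each gene, unlike in the percentage. The percentile therefore does not rank the percentage beside it, above all for lists with clustered genes. Its percentile was taken among 10000 random lists of protein-coding genes, matched gene by gene on the decile of the number of peaks nearby. A percentile describes these peak lists and is not a test, and random lists do not copy the clustering of the DLX and HOX genes. In all 152 pairs of a list and a contrast were computed.

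Genes were named by a rule fixed beforehand: up to 5 members per fixed list with the most peaks of a kind, the 10 protein-coding genes with the most peaks of a set assigned to their nearest annotated end within 100 kb, and the 5 peaks of highest fold in the sets that held across times. Tied members and other genes named outside the rule are marked as such. The gene maps show the top-ranked member of the immediate-early and of the GABAergic list. For the response shared by the cell types, the share of gained peaks of 1 cell type that overlapped a gained peak of the other was set beside 10000 random draws of as many peaks from the same list. Because a peak that the other cell type had at 0 min could hardly be gained there, gained peaks were also compared with the list's other peaks among those absent from the other's 0 min list, and lost peaks likewise with the later list.

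The counting was tested on simulated data made from the GABA list at 0 min: 3000 of 3000 planted gains and 2000 of 2000 planted losses were recovered, and merging gave the same 60806 regions as bedtools. Planted gains overlapped no peak of that list and planted losses were whole merged peaks, so full recovery checks the code only. Of 200 random gene lists with no planted effect, 9 lay above the 95th percentile and 9 below the 5th. Their gains and losses were drawn at random from 1 list. Neither check copies peaks near the calling threshold or the clustering of related genes. Alternatives to the overlap rule, the merging, the threshold, the list length, the windows and the chromosomes were run as planned, with others added after seeing the data. The software was python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.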

Results

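Open chromatin was mapped in human induced Glu and GABA neurons before KCl depolarisation and 30 and 90 min after it, with 3 libraries per cell type and time and 1 peak list for each of the 6 groups. The design asks which regions are accessible in each type of neuron and which change with activity. The Glu lists held 51605 merged peaks at 0 min, 51074 at 30 min and 60664 at 90 min. The GABA lists held 60806, 58648 and 66844. Median peak width lay between 717 and 937 bp and median fold enrichment between 14.2 and 17.1. From 24.9% to 29.3% of a list's peaks lay within 1 kb of an annotated gene end. There is no replication at the level of these lists and the read depth is unknown, so a difference between 2 lists is a difference between those lists.

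The first comparison asks how resting Glu and GABA neurons differ. Most open sites were common to both: 34210 of 51605 Glu peaks (66.3%, 95% interval 65.9 to 66.7) overlapped a GABA peak at 0 min, and 34533 of 60806 GABA peaks (56.8%, 56.4 to 57.2) overlapped a Glu peak. There were 17395 Glu-only peaks (33.7%, 33.3 to 34.1) and 26273 GABA-only peaks (43.2%, 42.8 to 43.6). The shared sites were often at gene ends and the others rarely. Of the shared Glu peaks 39.5% lay within 1 kb of a gene end, against 6.49% of the Glu-only peaks, and for GABA the values were 39.6% and 9.80%. Sites that stayed specific to a cell type through all 3 times numbered 5959 in Glu (11.5% of the 0 min list) and 10240 in GABA (16.8%). The GABA list was longer than the Glu list, which by itself adds GABA-only peaks.

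GABAergic identity genes were flanked mostly by GABA-only peaks. Near the 26 genes of this list lay 69 GABA-only and 19 Glu-only peaks, so that 21.6% were Glu-only (exact interval 13.5 to 31.6) against 35.7% near all protein-coding genes, and the list stood at percentile 2.26 of the random lists. More GABA-only than Glu-only peaks lay near 15 of the 26 genes, and the opposite held for 1. SLC32A1, the vesicular GABA transporter, had 13 GABA-only peaks and 0 Glu-only peaks. The folds of those peaks ran from 2.69 to 21.7, most of them below 9.32, the value under which 10% of that list lay. Some lay side by side over the gene, and those from 38725144 and from 38725967 were a single peak at 30 min. The count thus depends on how a region is split. DLX5 and DLX6, neighbouring homeobox genes of GABAergic development that can share peaks, each had 7 and 0. GAD1, which encodes a GABA-synthesising enzyme, had 6 GABA-only peaks and 1 Glu-only peak. ERBB4, GAD2 and MEIS2 tied at 5 GABA-only peaks, with 1, 1 and 2 Glu-only peaks. ZEB2 was the member with more Glu-only peaks, 5 against 3. This excess was not kept when a gene's span with 10 kb on each side replaced the 50 kb windows (33.3% against 36.5% for all genes). In lists cut to their top 50000 peaks by fold the share was 44.1% (32.1 to 56.7), an interval that included the 49.8% of all genes, at percentile 16.59. With 10 kb windows it was 15.4% (5.86 to 30.5) against 31.7%, at percentile 6.7. The excess was larger in lists cut by −log10 p (25.3% against 46.4%). Among peaks specific to a cell type at all 3 times the share was 21.7% (10.9 to 36.4) against 31.5% for all genes, at percentile 14.29, and in lists cut by fold it turned to 57.7% against 41.3%.

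Glutamatergic identity genes had 26 Glu-only and 34 GABA-only peaks. The Glu-only share of 43.3% (30.6 to 56.8) included the value for all genes, at percentile 90.67. The members differed from one another. FEZF2, a transcription factor of deep-layer cortical projection neurons, had 4 Glu-only and 0 GABA-only peaks, and SATB2, a transcription factor of cortical projection neurons, had 3 and 0. SLC17A6, the vesicular glutamate transporter VGLUT2, had 3 and 2, CUX2 had 3 and 4, and LMO3 had 2 and 1. RTN4RL1 had 2 Glu-only and 9 GABA-only peaks, and CAMK2A and SLA had 1 and 4 each. Among peaks specific to a cell type at all 3 times, 11 lay near the list in Glu and 10 in GABA, a share of 52.4% (29.8 to 74.3) against 31.5% for all genes, at percentile 97.09. That percentile was 89.9 with 10 kb windows, 79.66 with gene spans, 91.54 in lists cut by fold and 93.4 with distal peaks.

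**Figure D1:**
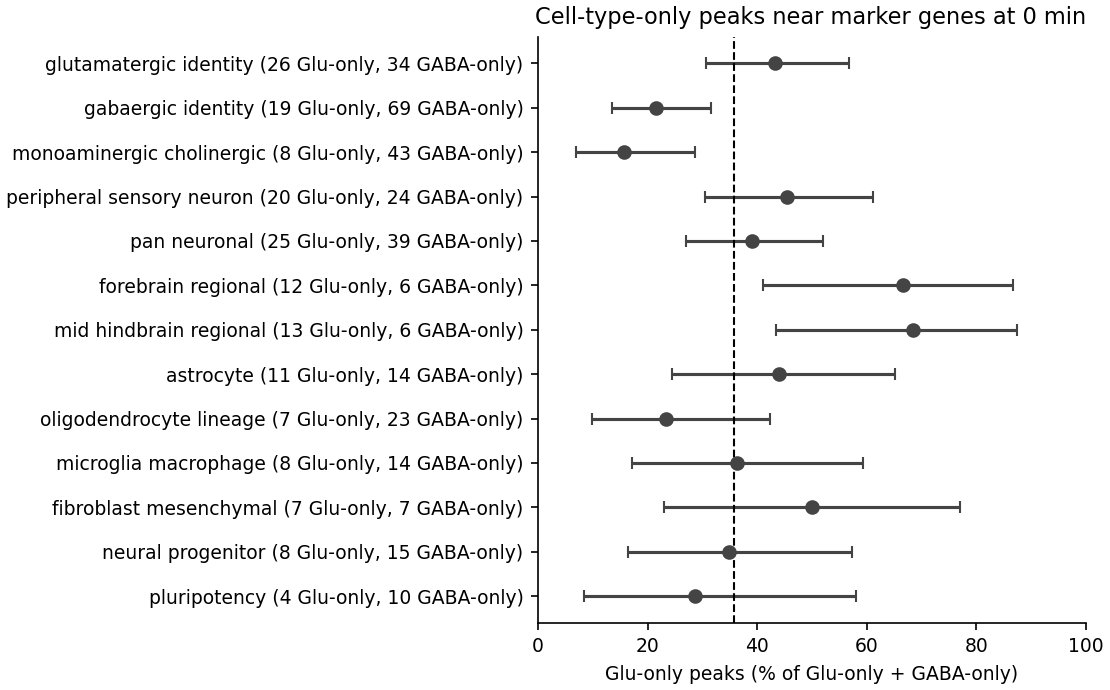
Glu-only peaks as a percentage of Glu-only plus GABA-only peaks within 50 kb of the ends of marker genes at 0 min (x axis, percent), 1 row per fixed list. Points are shares, bars are exact 95% binomial intervals (counting error over peaks), and the dashed line is the 35.7% found for all protein-coding genes. The intervals of the GABAergic (21.6%) and monoaminergic or cholinergic (15.7%) lists lie below the line, and those of the forebrain (66.7%) and mid-hindbrain (68.4%) lists above it.

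Genes of other transmitter systems also had GABA-only peaks nearby. The 12 genes of the monoaminergic and cholinergic list had 43 GABA-only and 8 Glu-only peaks (15.7%, 7.02 to 28.6, percentile 2.87), and each of the 12 genes had more GABA-only than Glu-only peaks. SLC6A5, a member of this list, encodes a glycine transporter and is neither monoaminergic nor cholinergic. DBH, which makes noradrenaline, had 7 GABA-only peaks and 1 Glu-only peak. FEV, a transcription factor of serotonergic neurons, had 5 and 0, TH, the rate-limiting enzyme of catecholamine synthesis, had 5 and 0, TPH2 had 5 and 2, and DDC had 4 and 1. Patterning genes went the other way. The 10 forebrain genes had 12 Glu-only and 6 GABA-only peaks (66.7%, 41.0 to 86.7, percentile 99.11), with 2 Glu-only peaks each at EMX2, LHX2, NR2F1 and OTX1. The 15 mid-hindbrain genes had 13 and 6 (68.4%, 43.4 to 87.4, percentile 99.98), with 4 Glu-only peaks at PAX2 and 3 each at HOXA1, HOXA2 and HOXB3, of which HOXA1 and HOXA2 are neighbours and share peaks. Both of these percentages rest on fewer than 20 peaks. The forebrain percentile was 93.83 with 10 kb windows and 91.61 with gene spans. In lists cut to 50000 peaks by fold the monoaminergic and cholinergic share was 42.1% against 49.8% for all genes, at percentile 24.12.

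For markers of cells other than neurons no lean either way was resolved, and the intervals are too wide to exclude one. The Glu-only share was 44.0% near astrocyte genes (24.4 to 65.1), 23.3% near oligodendrocyte-lineage genes (9.93 to 42.3), 36.4% near microglial genes (17.2 to 59.3), 50.0% near fibroblast genes (23 to 77), 34.8% near progenitor genes (16.4 to 57.3) and 28.6% near pluripotency genes (8.39 to 58.1), each interval including the 35.7% of all genes. The same held for the pan-neuronal genes (39.1%, 27.1 to 52.1), the sensory neuron genes (45.5%, 30.4 to 61.2), the GABA-A receptors (41.9%, 24.5 to 60.9), the ionotropic glutamate receptors (24.1%, 13.9 to 37.2) and the voltage-gated channels (33.9%, 22.3 to 47.0).

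The genes with the most cell-type-only peaks assigned at 0 min were GRIK3, a kainate receptor subunit, with 22 GABA-only peaks, TMEM132E with 15, GALNT10 with 14, TCERG1L with 13, and KCNMA1, KCNJ6, KIRREL3, NFASC and SLC32A1 with 12 each. On the Glu side ZNF608 had 10, NFIA, SDK2 and SKAP1 9 each, and BMPER, KIF16B, MVB12B and SYNPR 8 each. At SLC32A1 (chromosome 20, 38724486 to 38729372, GRCh38), a GABA-only peak at 0 min covered the gene's low-coordinate end, from 38723086 to 38724648. In Glu neurons a peak appeared at that end at 30 min (38724235 to 38724970) and at 90 min (38724243 to 38724950). The strongest Glu-only peak held at all 3 times lay between genes on chromosome 2 (145601294 to 145601838, fold 38.9), 1080 kb from the nearest protein-coding gene end, at ZEB2. The next 4 began with a peak on chromosome 2 (118319274 to 118319515, fold 34.6), 208 kb from INSIG2. A peak within KCNJ10 on chromosome 1 followed (160062212 to 160062500, fold 34.5). The others lay on chromosome 11, 23.5 kb from FAM181B (82757095 to 82757698, fold 32.8) and 28 bp from an end of HEPACAM (124935882 to 124936237, fold 32.5). KCNJ10 and HEPACAM are genes known for expression in astrocytes, and were picked out after the peaks were seen. The strongest GABA-only peak lay on chromosome 19 (58021783 to 58022220, fold 45), 11.9 kb from ZSCAN1.

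**Figure D2:**
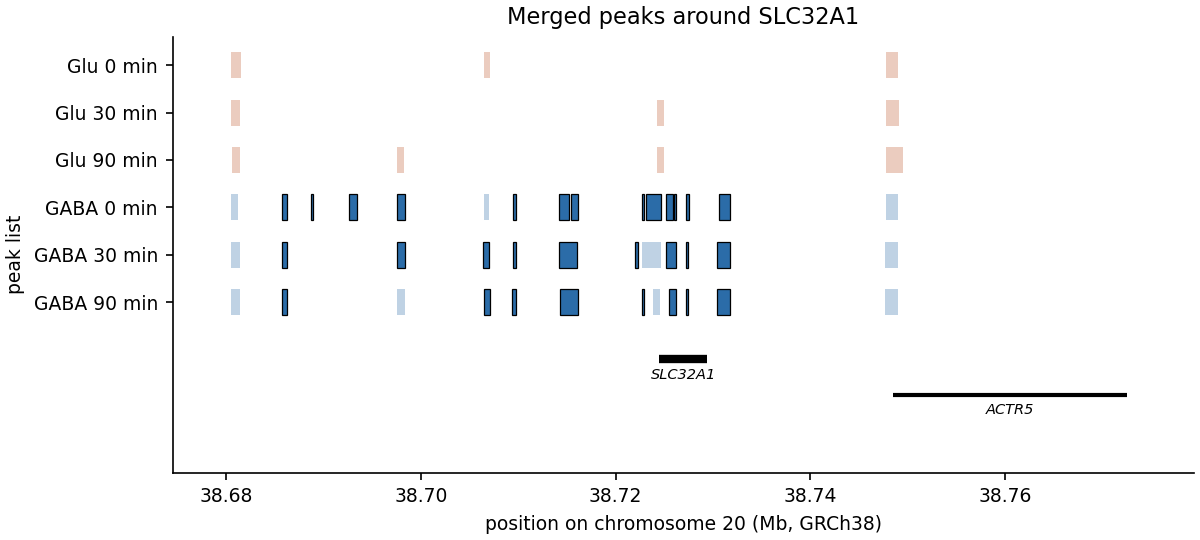
Merged peaks within 50 kb of SLC32A1 on chromosome 20 (x axis, Mb, GRCh38) in the 6 lists (rows). Dark outlined boxes overlap no peak of the other cell type at the same time, pale boxes do, and black bars are annotated protein-coding genes. The GABA list has 13 such dark boxes at 0 min and the Glu list 0.

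The second comparison asks which sites changed after depolarisation. At 30 min losses outnumbered gains, by little in Glu neurons (0.922 gained per lost peak) and more in GABA neurons (0.795). In the upper 50% of each list by −log10 p, a ranking added after seeing the data, the order turned, to 1.40 in Glu and 1.45 in GABA. In the upper 50% by fold it did not turn, with 0.945 in Glu and 0.753 in GABA. Glu neurons gained 7953 peaks (15.6% of the 30 min list, 15.3 to 15.9) and lost 8630 (16.7% of the 0 min list, 16.4 to 17.0), while GABA neurons gained 7295 (12.4%, 12.2 to 12.7) and lost 9172 (15.1%, 14.8 to 15.4). At 90 min gains exceeded losses, with 1.77 gained per lost peak in Glu and 1.37 in GABA: 20291 gained (33.4%, 33.1 to 33.8) and 11447 lost (22.2%, 21.8 to 22.5) in Glu, and 20706 gained (31.0%, 30.6 to 31.3) and 15067 lost (24.8%, 24.4 to 25.1) in GABA. Gains present at both 30 and 90 min numbered 3913 in Glu and 3583 in GABA, and losses at both times 5835 and 6925. Peaks stable over the 3 times made up 72.4% of the Glu and 71.5% of the GABA 0 min list. The 30 min lists were shorter than the 0 min lists and the 90 min lists were longer. A difference in list length by itself shifts the balance of gains and losses. The ratios over whole lists therefore do not show net closing at 30 min or net opening at 90 min. In lists cut to 50000 peaks gains and losses are nearly equal in number by construction. In those lists, ranked by fold, 31.7% of Glu and 31.4% of GABA peaks at 90 min were gained, against 16.2% and 13.3% at 30 min.

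**Figure D3:**
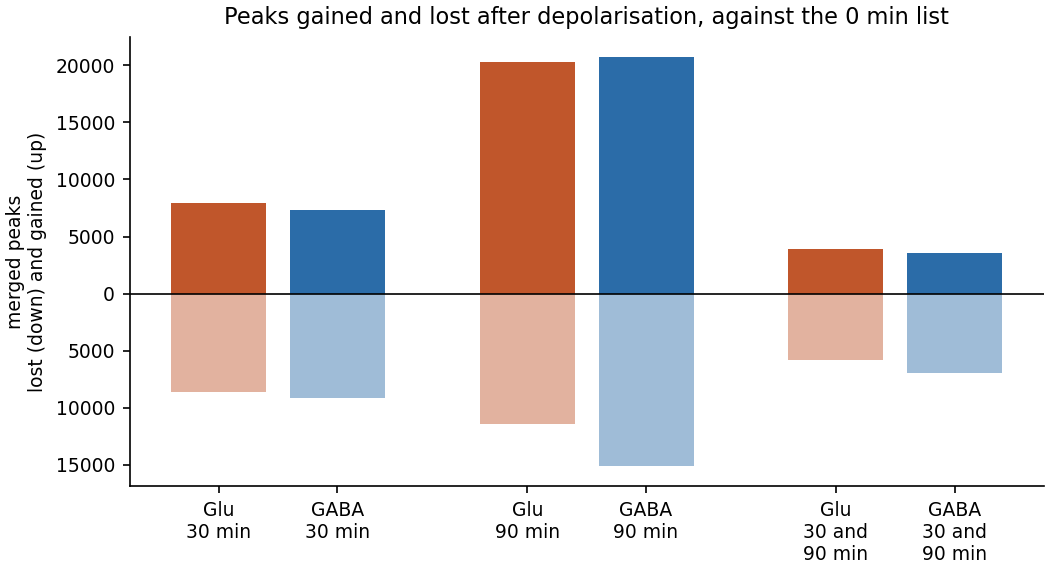
Number of merged peaks gained (dark bars, upward) and lost (pale bars, downward) against the 0 min list of the same cell type (y axis, peaks), for Glu (orange) and GABA (blue) at 30 min, at 90 min and at both times. Gains at 90 min reach 20291 in Glu and 20706 in GABA, against 7953 and 7295 at 30 min.

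Gained and lost sites were mostly distal. Within 1 kb of a gene end lay 11.7% of Glu gains at 30 min (11 to 12.5), 8.30% of Glu gains at 90 min (7.93 to 8.69), 12.7% of GABA gains at 30 min (11.9 to 13.4) and 7.87% of GABA gains at 90 min (7.51 to 8.24), against 35.9% and 33.9% of the stable peaks. At 30 min losses lay at gene ends less often than gains, 8.05% in Glu (7.50 to 8.65) and 6.86% in GABA (6.36 to 7.39). At 90 min the order was the other way, with 8.57% of losses in Glu (8.07 to 9.10) and 8.95% in GABA (8.51 to 9.42), although in Glu the intervals of gains and losses overlapped. Gained peaks at 30 min were weak ones, with a median fold of 10.7 in Glu and 11.4 in GABA where the lists had 14.2 and 16.8. At 90 min the medians were 13.7 and 15.7, against 15.1 and 17.1.

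Immediate-early genes, the first genes that neuronal activity switches on, had more gained than lost peaks around them in GABA neurons at 30 min. The 32 genes had 42 gained and 13 lost peaks, 76.4% gained (63.0 to 86.8) against 49.0% near all genes, at percentile 99.63. Gains outnumbered losses at 17 genes and losses outnumbered gains at 4. FOSB, a subunit of the AP-1 transcription factor, and NR4A1, an orphan nuclear receptor, gained 6 peaks each and lost 0. FOS gained 3 and lost 0, and EGR4 and JUND gained 3 and lost 1 each. CSRNP1 and FOSL1 lost 2 each. In Glu neurons at 30 min the list had 29 gained and 16 lost peaks (64.4%, 48.8 to 78.1, against 49.9%, percentile 93.49), with 4 gained and 1 lost at JUND, 2 and 0 at CSRNP1, 2 and 1 at FOS, 2 and 2 at EGR1, and 2 and 3 at JUNB. Whether the cell types differed in this was not tested. At 90 min GABA neurons had 58 gained and 24 lost peaks near the list (70.7%, 59.6 to 80.3, against 57.3%, percentile 99.62), with 7 gained at KLF6, 6 at FOSB, 4 each at ARC and JUND, and 3 at CSRNP1. Glu neurons had 41 and 21 (66.1%, 53.0 to 77.7, against 62.9%, percentile 75.74), with 4 gained each at FOSB, KLF6 and NPAS4 and 3 each at ARC and CSRNP1.

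The immediate-early gains depend on how peaks are ranked. Those in GABA neurons at 30 min had a median fold of 4.71, above 1.69% of their list, and a median −log10 p of 83.4, above 18.2% of it. In lists cut to their top 50000 peaks by fold the list turned to 36.7% gained at 30 min (11 gained and 19 lost, against 55.1% for all genes) and 24.6% at 90 min (against 46.0%). Of those losses 15 of 19 at 30 min and 39 of 49 at 90 min were still in the full later list, below the cut, and 7 of the 11 gains were in the full 0 min list. In Glu at 90 min it turned to 20.0% (16 gained and 64 lost, against 44.9%, percentile 0.4). In lists cut by −log10 p it stood in GABA at 88.2% (30 gained and 4 lost, against 54.7%) and 58.3% (against 47.2%). With 100 kb windows the GABA share at 90 min was 61.5% (52.7 to 69.7, against 57.8%, percentile 89.56). The 14 housekeeping genes also had more gained than lost peaks at 30 min, 7 and 1 in GABA (87.5%, 47.3 to 99.7, percentile 99.08) and 9 and 2 in Glu (81.8%, 48.2 to 97.7, percentile 98.39). In lists cut by fold the GABA value was 57.1% (percentile 44.42), while the Glu value stayed at 81.8% (percentile 96.53). The immediate-early list in Glu at 30 min stood there at 56.4% (against 52.5%, percentile 55.52). For the housekeeping genes, in lists cut by −log10 p the percentiles were 75.73 in GABA and 89.37 in Glu, and with 100 kb windows 89.06 and 96.72.

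**Figure D4:**
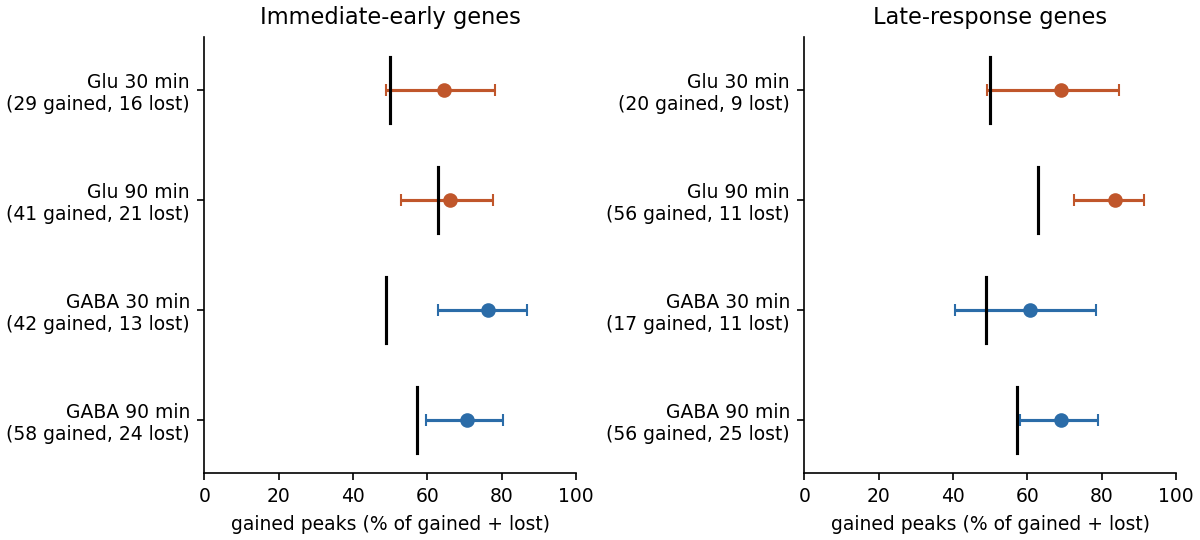
Gained peaks as a percentage of gained plus lost peaks within 50 kb of the ends of immediate-early (left) and late-response (right) genes (x axis, percent), by cell type and time. Points are shares, bars exact 95% binomial intervals (counting error over peaks), and black ticks the share near all protein-coding genes. The interval lies above the tick for immediate-early genes in GABA at 30 min (76.4%) and 90 min (70.7%), and for late-response genes in Glu (83.6%) and GABA (69.1%) at 90 min.

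At FOSB (chromosome 19, 45467996 to 45475179, GRCh38) both cell types gained a peak at the high-coordinate end of the gene at 30 min, from 45474615 to 45476435 in Glu (fold 3.83) and from 45474345 to 45476204 in GABA (fold 3.07). Neither 90 min list had a peak there. A peak over the low-coordinate end of PPM1N (45498411 to 45499391 at 30 min) and a pair inside ERCC1 (45443076 to 45443920 and 45444135 to 45444703) were gained in GABA neurons at 30 min and seen again at 90 min. At 90 min both cell types had gained a peak between ERCC1 and FOSB, from 45455744 to 45456284 in Glu (fold 9.25) and from 45455743 to 45456260 in GABA (fold 10.9).

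**Figure D5:**
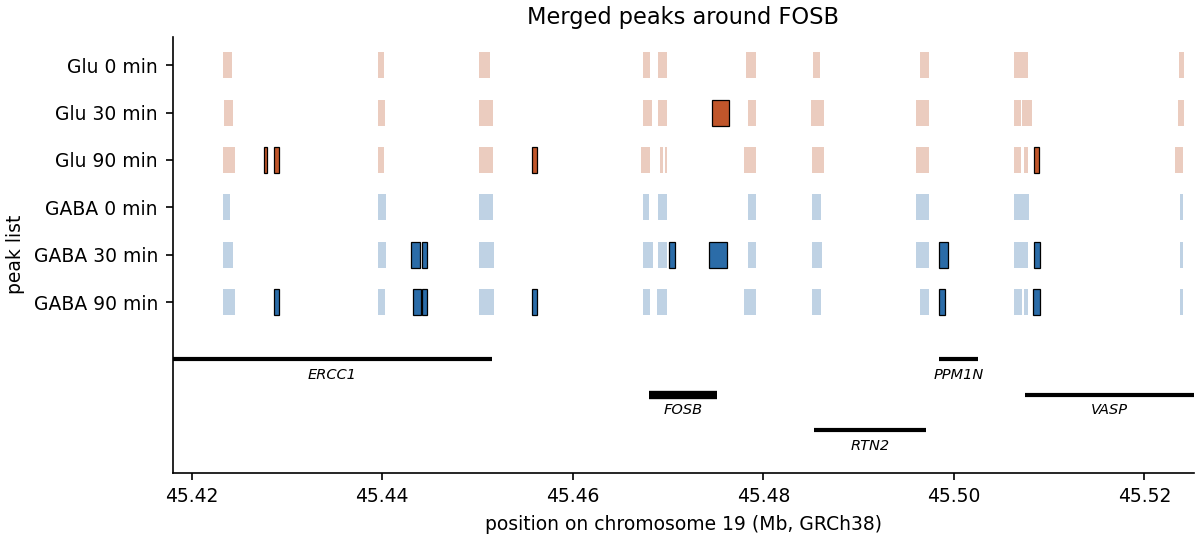
Merged peaks within 50 kb of FOSB on chromosome 19 (x axis, Mb, GRCh38) in the 6 lists (rows). Dark outlined boxes overlap no peak of the same cell type at 0 min, pale boxes do, and black bars are annotated protein-coding genes. GABA neurons have 6 gained peaks at 30 min and 6 at 90 min, and Glu neurons 1 and 4.

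Late-response genes, which include neuropeptides, growth factors and signalling regulators induced after the first wave, had mostly gained peaks around them at 90 min. In Glu neurons the 30 genes had 56 gained and 11 lost peaks, 83.6% gained (72.5 to 91.5) against 62.9% near all genes, at percentile 99.86. Gains outnumbered losses at 18 genes, and losses outnumbered gains at 1. SCG2, the secretogranin II precursor, gained 6 peaks and lost 0, and PDYN, the dynorphin precursor, gained 5 and lost 1. CREM, a cAMP-responsive transcription factor, DUSP4, a MAP kinase phosphatase, and GADD45B gained 4 each and lost 0, and PCSK1 and VGF tied with them at 4 gained. In GABA neurons there were 56 gained and 25 lost peaks (69.1%, 57.9 to 78.9, against 57.3%, percentile 97.41), with 6 gained and 2 lost at PDYN, 4 and 0 at NFIL3, 4 and 1 at MMP1, 4 and 2 at VGF, and 3 and 3 at DUSP4. BDNF, a growth factor of neuronal activity named here after its values were seen, had 3 gained and 1 lost in Glu and 2 gained and 3 lost in GABA at 90 min. At 30 min the list had 20 gained and 9 lost in Glu (69.0%, 49.2 to 84.7, percentile 95.89) and 17 and 11 in GABA (60.7%, 40.6 to 78.5, percentile 82.92), with 3 gained at SCG2 in Glu and 4 at HOMER1 in GABA. The Glu value was 54.5% with 10 kb windows (against 54.6%, percentile 48.05), and its percentile was 74.83 with gene spans and 89.62 in lists cut by −log10 p. With equal list lengths by fold the 90 min share was 55.1% in Glu (against 44.9% for all genes, percentile 95.11) and 52.6% in GABA (against 46.0%, percentile 89.61). With 10 kb windows it was 73.9% in Glu (51.6 to 89.8, against 61.1%, percentile 86.72) and 66.7% in GABA (48.2 to 82.0, against 55.3%, percentile 84.09), and with gene spans 72.4% (percentile 83.48) and 64.1% (percentile 78.36).

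Among peaks that held at both times, late-response genes had 16 gained and 3 lost in Glu (84.2%, 60.4 to 96.6, against 41.7%, percentile 99.84) and 12 and 4 in GABA (75%, 47.6 to 92.7, against 37.8%, percentile 99.61). With 10 kb windows the Glu value was 71.4% (29.0 to 96.3, percentile 87.1), and with gene spans its percentile was 94.49. The GABA value was 48.4% with 100 kb windows (against 36.6%, percentile 87.31), and its percentile was 85.17 in lists cut by fold and 93.77 in lists cut by −log10 p. Immediate-early genes had 19 and 11 in GABA (63.3%, 43.9 to 80.1, percentile 98.17), among them FOSB with 4 and 0 and JUND with 3 and 1. The 4 peaks counted near FOSB lay within ERCC1 and VASP and at an end of PPM1N, and none lay at FOSB itself. In Glu the immediate-early genes had 17 and 12 (58.6%, percentile 91.48), with an interval of 38.9 to 76.5 that includes the share of all genes, and more gains at 9 genes and more losses at 7. Cut to 50000 peaks by fold, the GABA share turned to 18.8% (against 37.8%), and with distal peaks it was 47.4% (percentile 81.95). Near the GABAergic list Glu neurons had 25 gained and 9 lost peaks at 30 min (73.5%, 55.6 to 87.1, against 49.9%, percentile 98.09), with 4 gained at ZEB2, 3 at MEIS2 and 2 each at ARX, GAD1 and SLC6A1. With gene spans this was 62.1% (against 51.2%, percentile 81.5). At 90 min the same list had 29 and 14 (67.4%, 51.5 to 80.9, against 62.9%). In GABA neurons it had 11 and 11 at 30 min and 27 and 23 at 90 min. The oligodendrocyte-lineage list stood about as high in Glu at 30 min, with 7 gained and 1 lost (87.5%, 47.3 to 99.7, percentile 97.97). Among the 152 pairs computed, some outer percentiles would arise without any effect.

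Counts of peaks assigned to the nearest gene end depend on a gene's span and spacing and were not tested. By this count BACH2, a transcriptional repressor of the BTB and CNC family, led at 90 min in both cell types, with 12 gained peaks assigned in Glu and 17 in GABA. In Glu it was followed by ZSWIM6 with 11 and by LARGE1, XYLT1 and the pan-neuronal gene ELAVL4 with 10 each. In GABA it was followed by ZMIZ1 with 15, CADM1 with 12, and ARID1B, EGFR, IGSF21, KCND3, SORL1 and the pan-neuronal gene NCAM1 with 11 each. At 30 min SKAP2 had 8 in Glu, and SIPA1L2, SYT13 and ZNF608 had 6 each in GABA. TMEM132E had the most losses at 90 min in GABA, 14, and lost 8 in Glu, where SDK2 lost 11. GRIK3 and MVB12B lost 10 each in GABA at 90 min. The strongest peak gained at both times lay on chromosome 1 in Glu (162790352 to 162790624, fold 29.1), 177 bp from an end of HSD17B7, and on chromosome X in GABA (43481492 to 43482010, fold 34.7), 173 kb from MAOA. The strongest peak lost at both times in Glu (chromosome 5, 60761878 to 60762037, within ELOVL7) had a fold of 52.0 with an IDR score of 574, near the lowest score kept. In GABA it lay on chromosome 8 (81883436 to 81884067, fold 30.0), 41.7 kb from SNX16.

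The third comparison asks how much of the response the cell types had in common. At 90 min 7332 of 20291 Glu gains (36.1%, 35.5 to 36.8) overlapped a GABA gain, and 7351 of 20706 GABA gains (35.5%, 34.9 to 36.2) overlapped a Glu gain. Random draws from the same lists gave 15.5% and 16.2%, but they include peaks that the other cell type had at 0 min and so could hardly gain. Among peaks absent from the other cell type's 0 min list, 44.1% of Glu gains (43.4 to 44.9) overlapped a GABA gain, against 19.3% of the other Glu peaks (18.5 to 20.0). For GABA the shares were 39.8% (39.1 to 40.5) and 21.7% (21.1 to 22.4). The other peaks here were already open at 0 min in their own cell type and absent from the other. They were thus sites specific to a cell type at rest, which could by itself lower their share. The comparison therefore cannot tell a common response from this choice of peaks. At 30 min the intervals of gains and of other peaks chosen in this way overlapped. The shares were 11.9% of gains (11 to 12.8) and 12.4% of other peaks (11.8 to 13.0) in Glu. In GABA they were 11.7% (10.9 to 12.6) and 11.3% (10.9 to 11.8). Of all gains 8.17% in Glu and 8.92% in GABA were shared at 30 min, and the random draws gave 4.23% and 4.89%. Losses at 90 min were shared more often than random draws, 15.7% against 8.57% in Glu and 12.0% against 6.47% in GABA, but not more often than other peaks that could be shared. Among peaks absent from the other cell type's later list, 19.5% of Glu losses (18.7 to 20.4) and 14.8% of GABA losses (14.2 to 15.5) at 90 min overlapped a loss of the other, against 23.8% (23 to 24.7) and 14.6% (14.1 to 15.2) of the peaks kept. The peaks kept were open at the later time in their own cell type and absent from the other, so a similar limit applies. At 30 min the shares were 8.86% of losses against 13.6% of kept peaks in Glu, and 7.66% against 11% in GABA. This comparison was added after the data were seen. Of the Glu gains at 90 min 18.5% were at sites already open in GABA neurons at 0 min, 36.1% opened there by 90 min, and 45.4% had no GABA peak at either time. For the GABA gains these shares were 10.8%, 35.8% and 53.4%.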

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

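The peak counts, the shares of common gains and losses and 22 contrasts of a gene list were recomputed under other settings, which gave 428 values, of which 340 stayed the same, 85 moved and 3 reversed. A count stayed the same within 1.5 times the main count and a share within its 95% interval. A gene-list share reversed when its main interval excluded the share of all genes and the new value crossed to the other side of that share. Shares that crossed without such a main interval count as moved or the same. The remaining pairs of a list and a contrast were not recomputed. No paired analysis was possible because each group has 1 peak list and no value per library, and leaving out a replicate and the motif alternatives were not run for want of per-library data and of the genome sequence. Planned settings were the overlap rule, unmerged entries, the stronger peaks by fold, lists cut to the top 50000 peaks by fold, distal peaks for the peak counts, autosomes, and windows of 10 kb, 100 kb and the gene span. Settings that rank or cut by −log10 p, use a common p floor, use distal peaks near gene lists, use peaks outside the list genes or leave out 1 gene were added after seeing the data, as were 12 of the 22 contrasts. By this measure nothing moved with a gap allowed, summit overlap, autosomes, distal peaks, the common p floor or 100 kb windows. Percentiles were less stable: of 16 contrasts at 95 or more or at 5 or less, 10 stayed there with 100 kb windows, 11 with distal peaks, 5 with 10 kb windows, 6 with gene spans, 7 with lists cut by fold and 11 with lists cut by −log10 p. Late-response genes in GABA stood at 48.0% (against 47.5%) at 30 min with 100 kb windows and at percentile 92.94 at 90 min with distal peaks. Where values moved, the cause was not tested unless the setting changes the number counted by construction.

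Unmerged entries multiply the counts by construction: 44825 Glu-only and 68511 GABA-only entries at 0 min, 17103 and 28740 at all 3 times, 19850 gained and 19744 lost at 30 min in Glu and 16407 and 20255 in GABA, 45925 and 26923 at 90 min in Glu and 46546 and 35179 in GABA, and 10427 and 12916 at both times in Glu and 8438 and 15023 in GABA. The upper 50% of each list by fold lowers them by construction: 5752 Glu-only and 9446 GABA-only peaks at 0 min, 2918 and 5659 at all 3 times, 1243 gained and 1315 lost at 30 min in Glu and 800 and 1063 in GABA, 7679 and 2391 at 90 min in Glu and 8435 and 2954 in GABA, and 834 and 786 at both times in Glu and 617 and 644 in GABA. The upper 50% by −log10 p gave 360 gained and 258 lost at 30 min in Glu and 129 and 89 in GABA, and 4695 and 753 at 90 min in Glu and 4815 and 794 in GABA. Cutting to 50000 peaks by −log10 p gave 5395 GABA losses at 30 min, 13267 GABA gains at 90 min and 4514 GABA losses at both times.

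Near the gene lists, cutting to 50000 peaks by fold gave gained shares of 20.0% (against 44.9% for all genes) for immediate-early genes in Glu at 90 min, 36.7% (reversed) in GABA at 30 min and 24.6% (reversed) in GABA at 90 min, and of 55.1% and 52.6% for late-response genes at 90 min in Glu and GABA, with Glu-only shares of 44.1% for GABAergic (57.7% at all 3 times, against 41.3%), 42.1% for monoaminergic and cholinergic and 87.5% for forebrain genes. For immediate-early genes at both times it gave 31.6% in Glu and 18.8% (reversed) in GABA. Cutting by −log10 p gave 48.1%, 88.2% and 58.3% for the same immediate-early contrasts, 67.3% for late-response genes in Glu at 90 min, 81.2% for immediate-early genes in GABA at both times and 78.6% for glutamatergic genes at all 3 times. Gene spans with 10 kb on each side gave 72.4% for late-response genes in Glu at 90 min, 78.6% in GABA at 30 min, 33.3% for GABAergic and 90.0% for mid-hindbrain genes, and 100% for housekeeping genes at 30 min in both cell types, from 2 and 3 peaks. Windows of 10 kb gave 81.8% for late-response genes in GABA at 30 min, 87.5% for mid-hindbrain genes and 100% for housekeeping genes at 30 min in both cell types, as did leaving out GAPDH in GABA, and peaks outside the list genes 92.3% in Glu at 90 min. The share of 90 min gains common to both cell types was 33.6% in Glu and 32.5% in GABA with reciprocal overlap, 34.9% in Glu with lists cut by fold, and 34.8% in Glu and 36.4% in GABA with lists cut by −log10 p, which gave 11.4% for GABA gains at 30 min.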

Other observations

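The tests of late-response genes, of the other 90 min gains and of weak peaks were chosen only after the result was seen, as were the rankings by −log10 p and the gene-list counts of distal peaks and of peaks outside the spans of a list's own genes.

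Most 90 min gains were absent at the middle time, called 30 min here: 16333 of the 75600 regions ever open in Glu neurons, and 16983 of 84570 in GABA neurons, were seen at 90 min alone, against 3864 and 3548 seen at 30 and 90 min. Another 4040 Glu and 3712 GABA regions were seen at 30 min alone, and 2785 and 2238 were missing at 30 min alone, counts that include peaks near the calling threshold. Inside FOSB, the fold at the summit of the GABA peak from 45468959 was 15.7 at 0 min, 5.32 at 30 min and 7.78 at 90 min (Glu 17.6, 5.56 and 10.1). That of the peak beyond the gene from 45478353 was 31.8, 11.6 and 17.7 (Glu 22.2, 8.44 and 15.0). In GABA its summit was 45478654 at 0 min but 45479097 at 90 min. The GABA peak at the low-coordinate end of FOSB from 45467385 had 9.22, 7.12 and 8.20 (Glu 8.78, 7.28 and 9.56). The GABA peak at the end of RTN2 from 45485133 had 31.5, 30.9 and 26.0 (Glu 21.4, 16.7 and 17.4). These folds come from separately called lists of unknown depth and are not a measured course over time.

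The excess of gains at 90 min could come from a longer list of weak peaks, from a technical difference of the 90 min libraries, or from opening of chromatin after depolarisation. A list padded with weak peaks predicts no excess over 30 min among strong ones, yet in the upper 50% of each list, by fold or by −log10 p, the share gained at 90 min was at least 5.2 times that at 30 min. A technical difference blind to gene function predicts no lean at late-response genes, and the list stood at percentile 99.86 in Glu neurons and 97.41 in GABA neurons. With 10 kb windows it stood at 86.72 and 84.09, with gene spans at 83.48 and 78.36, and in GABA at 89.61 in lists cut to equal length by fold, so the explanations cannot be told apart near these genes. Over all peaks, those near late-response genes included, 1.37 were gained per lost peak in the cell type with the lower ratio. The gains away from these genes were not counted separately. For them time and library preparation vary together, so the explanations cannot be told apart either. Per-library peak counts with the preparation dates, or a mock-treated culture at 90 min, would separate the explanations.

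The gains near immediate-early genes in GABA neurons at 30 min might be part of a gain at gene ends of any kind, since the housekeeping list had 7 gained and 1 lost. With distal peaks alone, 23 gained and 12 lost, the list stood at percentile 96.06 (65.7% gained, 47.8 to 80.9, against 46.8%). These lists thus kept a lean away from gene ends. The interval starts close to the share of all genes, so the part played by gene ends stays open. Opening confined to the spans of the transcribed genes predicts no lean outside the spans of the list's own genes, where the list stood at 99.84 (79.1%, 64.0 to 90.0, against 49.0%). Peaks were placed by summit, so a peak over a gene's end can count as outside. The FOSB peak from 45474345 to 45476204, with its summit at 45475310, did so. Opening at the genes' own ends was therefore not excluded. Weak peaks on either side of the calling threshold remain possible: with equal list lengths the list stood at percentile 1.91 by fold and 99.79 by −log10 p, and these cannot be told apart without reads. A local background raised by reads from active genes could lower the fold there, and coverage per library over FOSB and NR4A1 would show it.

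Strong narrow (up to 400 bp) Glu-only peaks lie at KCNJ10 and HEPACAM, which may reflect reads of the mouse glia, glial-like human cells, or regulation in neurons. The strong Glu-only peak 208 kb from INSIG2 was narrow as well. Of the narrow peaks near astrocyte genes 3 were Glu-only and 1 GABA-only (75%, 19.4 to 99.4, against 31.9% for all genes), at percentile 92.77, and with 4 peaks the explanations cannot be told apart. Narrow peaks made up 6.94% of Glu-only peaks (6.58 to 7.33), 4.77% of the strongest 10% of them (3.86 to 5.88) and 4.71% of the whole Glu list, against 11.1%, 3.35% and 8.99% in GABA. Alignment of the reads to a joined human and mouse genome would separate them.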
